A study of Homo sapiens with 5 samples.

How the data were processed

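Total RNA of SiHa cells (200 ng per sample, per the labels' protocols) was labelled with cyanine 3 and hybridised to Agilent 1-colour human miRNA arrays, 1 sample per array. The array design was 070156, per the file headers. The labels name Agilent Feature Extraction, and its version was 11.5.1.1, per the file headers. The scanner files as deposited hold spot intensity values that were spatially detrended and background-subtracted and were not scaled between arrays. They also hold mean and background spot intensity and Agilent's total gene signal per miRNA, a summed intensity with a floor of 0.1 where a miRNA was not detected. Flags of 0 or 1 in the same deposited files mark spots well above background, saturated spots and outliers.

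The deposited value table holds log2 values. Set against each array's total gene signal, it equalled the log2 of that signal plus 1 constant per array, except for 1 to 3 miRNAs per array whose signals lay between 0.1 and 1. The constants were 3.32, -0.98 and 3.32 for DMSO replicates 1, 2 and 3, and 3.32 and -1.19 for emodin replicates 1 and 2. The column medians were 0, -4.30, 0, 0 and -4.51 in the same order. Each constant lay within 0.0322 of minus the log2 of that array's 90th percentile over 2570 entries, and on the arrays with the constant 3.32 that percentile is the floor of 0.1. Which step made the constants is not given in the sources used here. Because the constants differ by over 4 log2 units within each group, the table served only as an alternative.

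Control spots and spots with an outlier flag (3.33% of the 50980 miRNA spots) were left out, and no miRNA spot was saturated. A probe counted as detected where more than 0.5 of its spots were well above background, and a miRNA where any of its probes was. Each array's signal was divided by its 75th percentile over the 166 probes detected on all arrays and multiplied by the geometric mean of those percentiles. Values were then set to at least 1 and taken to log2. Spots of a probe were averaged, then the probes of a miRNA, of which there are 1 to 4. No called miRNA had probes of opposite sign, but the size of change could differ between probes. Probe values were 1.59 and 1.59 for miR-181a-5p, but 1.61 and 3.19 for miR-25-3p and 1.00 and 2.90 for miR-193b-3p. The standard errors do not include this spread between probes. miRNAs detected on every array of at least 1 group were kept, 155 of 2549. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, plain prior, 3 residual degrees of freedom), adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05. All fold changes are emodin minus DMSO on this log2 scale, ± the standard error of the fit. For a miRNA detected on every array of 1 group and none of the other, the fold is a lower bound. Its bright group's mean was set against the dim group's mean of, per array, the higher of its own value and the lowest value among detected probes. For the named miRNAs detected on some arrays of 1 group, the difference with that group's values raised in this way is given with the fitted value.

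The design, test, lists and naming rule were fixed before the data were examined, as were the alternatives except those that the sensitivity part names as chosen later. The text names called miRNAs whose groups do not overlap and that are detected in both groups, up to 12 per direction by size of change, filled to 6 by smallest p. It also names up to 5 per direction detected in 1 group alone, the 10 brightest in DMSO, and up to 4 members of each list with the smallest p. The 19 lists were the let-7 family, the cluster of miR-17 to miR-92a with its paralogous clusters, the miR-200 family with other epithelial miRNAs, TGF-beta and EMT associated miRNAs, p53-responsive miRNAs, the miR-15/16 family, the miR-23/27/24 clusters, the miR-29 and miR-30 families, and the miR-99/100 and miR-125 families. The others were hypoxia and redox miRNAs, inflammation miRNAs, miRNAs reported as lower and as higher in cervical cancer, markers of other cell types, stromal miRNAs, the 14q32 cluster, the C19MC cluster, GC-rich array miRNAs as a sign of RNA quality, and fragments of other RNAs. Of their 291 entries 5 had no match on the array. The 12 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01. With an estimated correlation camera called 0 lists, as did fry, which tests whether members move one way on balance. fry's test for change in either direction gave adjusted p values of 0.00999 for the TGF-beta and EMT list, 0.0334 for the list of the miR-17 to miR-92a cluster and 0.0389 for the cervical cancer list reported as higher.

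DMSO replicates 1 and 3 resembled each other more than the other pairs, with a correlation of 0.987 over the 155 tested miRNAs. The SD of their log2 difference was 0.241 over 166 probes. Their squared differences were on average 17.2 times the spot noise, against at least 255 times for every other pair, so they were not treated as 1 array listed under 2 labels. A repeat hybridisation of 1 RNA would also exceed spot noise, so these values do not show whether the RNA came from separate cultures, and averaging the pair was tried as an alternative. Replicate numbers are shared between groups in the labels, but no label says that they mark a shared culture or day, so the main design had no block. Before scaling, the 75th percentile signal was 866 on DMSO replicate 2 and 612 on emodin replicate 2, against 227 to 232 on the other arrays. Whether the arrays numbered 2 share a batch cannot be told from the labels, and a replicate block was run as an alternative.

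The steps were tested on simulated data in 20 runs shaped like the comparison of emodin with DMSO, with 30 changed miRNAs per run among a median of 143.5 tested. They called 32% of 2-fold changes, 94.2% of 4-fold changes and 100% of 8-fold changes. A further single run in which nothing was changed gave 0 calls. On average 6.27% of calls were false. The simulated noise was drawn independently for each miRNA with 1 SD, 0.486. It held no difference shared by many miRNAs, as between DMSO replicate 2 and the other DMSO arrays, so these rates may not hold for the real arrays. Probe positions are as the files give them, with hg19 named in the headers, and were not checked against that build. Of the 155 tested miRNAs, 78 have a mapped probe. Many miRNAs have copies at further loci, and no genome or gene coordinates were used. Alternatives covered the scaling, background correction, probe summary, filter, floor, prior, replicate block and omission of each array in turn.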

Results

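Mature microRNAs (miRNAs) were measured in SiHa cells, a human papillomavirus-positive cervical carcinoma line, 24 h after treatment with emodin, a plant anthraquinone. Control cells received the vehicle, 0.4% dimethyl sulphoxide (DMSO). The emodin dose is not given in the sources used here. RNA of DMSO-treated cells was hybridised to 3 arrays and RNA of emodin-treated cells to 2 arrays, each carrying probes for 2549 human miRNAs. DMSO replicates 1, 2 and 3 gave 140, 218 and 136 miRNAs above background, and emodin replicates 1 and 2 gave 135 and 235. Of all miRNAs, 108 were detected on all 5 arrays and 2288 on none, and 155 were detected on every array of at least 1 group and were tested. The number of arrays limits the precision of every value, and no label says that the replicates came from separate cultures, so p-values measure only the spread between these arrays. All DMSO arrays lay on slide 1 and both emodin arrays on slide 2, so slide and treatment cannot be told apart.

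The comparison asked which miRNAs differ 24 h after emodin. In limma's test with Benjamini-Hochberg adjustment 24 of the 155 miRNAs changed, of which 19 were higher and 5 lower after emodin. miR-25-3p, which is encoded in an intron of the replication factor gene MCM7, rose from a normalized log2 signal of 3.99 ± 0.64 (SD, n = 3) in DMSO to 6.39 ± 0.28 (SD, n = 2) after emodin, a log2 fold change of 2.40 ± 0.47 (SE, adjusted p = 0.0135). Its probes stood at 1.61 and 3.19, and its call was lost when the brightest probe alone was used. miR-222-3p and miR-221-3p, a pair encoded side by side that represses the cell cycle inhibitor CDKN1B, rose by 2.05 ± 0.44 (adjusted p = 0.0208) and 1.60 ± 0.44 (adjusted p = 0.0322), though with scaling to spike-in controls the value of miR-221-3p was -0.44. miR-30c-5p and miR-30b-5p rose in the test (2.80 ± 0.49 and 2.54 ± 0.49, adjusted p = 0.0132 and 0.0135), but like miR-222-3p and miR-221-3p they were detected on 1 of 3 DMSO arrays, and with DMSO values raised to each array's lowest detected signal their differences were 0.34 and 0.58, and 0.80 and 0.83 with the emodin values raised in the same way (adjusted p = 0.408 and 0.396). Among the 5 miRNAs that fell was let-7e-5p, from 10.48 ± 0.29 (SD, n = 3) in DMSO to 8.91 ± 0.60 (SD, n = 2) after emodin, a log2 fold change of -1.57 ± 0.45 (adjusted p = 0.0366).

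Further rises were those of miR-193b-3p (log2 fold change 1.95 ± 0.45, adjusted p = 0.0234), miR-181a-5p (1.59 ± 0.41, adjusted p = 0.0234), miR-1273g-3p (1.76 ± 0.44, adjusted p = 0.0234) and miR-6869-5p (1.77 ± 0.56, adjusted p = 0.0493). miR-6125, miR-2861 and miR-197-3p were detected on both emodin arrays and were not well above background on any DMSO array. Their calls came from fitted values that used DMSO signals below detection (limma adjusted p = 0.0234, 0.0412 and 0.0234). Against the lowest detected signal of the DMSO arrays they were at least 2.72-fold, 2.15-fold and 1.49-fold higher after emodin. With every value raised to its array's lowest detected signal they were not called in limma (adjusted p = 0.200, 0.298 and 0.571). miR-6090 and miR-4665-3p, also detected on emodin arrays alone, had bounds of at least 1.64-fold and 1.07-fold and were not called (adjusted p = 0.189 and 0.269). Besides let-7e-5p, the miRNAs that fell were miR-1973 (-2.30 ± 0.68, adjusted p = 0.0412), miR-4485-5p (-1.82 ± 0.54, adjusted p = 0.0412), miR-6763-5p (-1.74 ± 0.46, adjusted p = 0.0280) and miR-4306 (-1.70 ± 0.43, adjusted p = 0.0234). miR-1973 and miR-4306 were detected on 1 of 2 emodin arrays, and with emodin values raised to the lowest detected signal their differences were -0.43 and -1.41. The value of miR-1973 was -0.77 without emodin replicate 1 (adjusted p = 0.458) and -3.67 without emodin replicate 2 (adjusted p = 0.000815, with 0.934 the highest over its alternatives), and that of miR-4485-5p was -1.08 without emodin replicate 1 (adjusted p = 0.388). The next miRNA in that direction, miR-6879-5p, had a log2 fold change of -1.25 ± 0.41 and was not called (adjusted p = 0.0558).

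**Figure D1:**
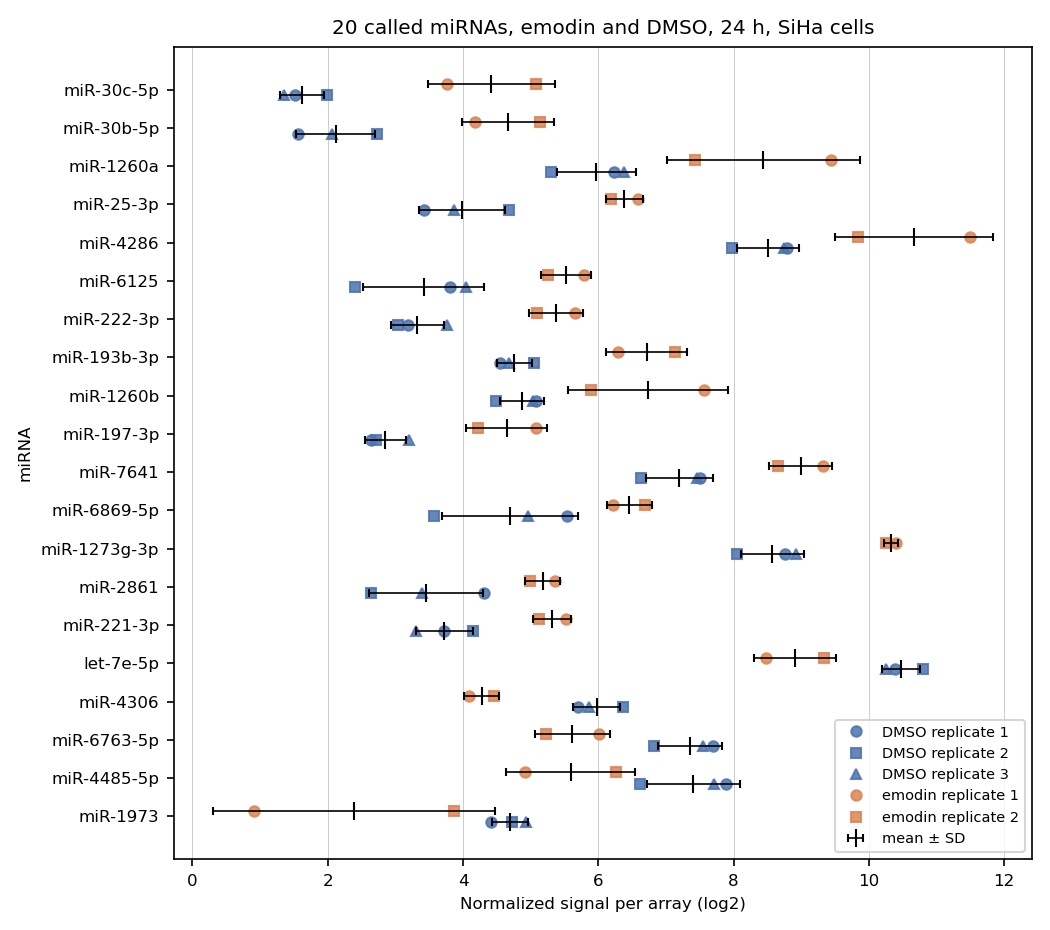
Normalized log2 signal (horizontal axis) of 20 called miRNAs (vertical axis) on each DMSO array (blue) and emodin array (orange), with marker shapes for replicates and black bars for mean ± SD. For every miRNA drawn, the emodin arrays lie on one side of all DMSO arrays; with scaling to the labelling spike-in controls 8 of the rises drawn had values below 0, and miR-30c-5p, miR-30b-5p, miR-222-3p and miR-221-3p were each detected on 1 of 3 DMSO arrays.

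In all 24 called miRNAs the groups did not overlap, as they did not in 57.4% of the tested miRNAs, where exchangeable arrays would give 20%. The excess does not measure a response to emodin. Tested miRNAs share array-wide differences, each group lay on its own slide, and the filter kept miRNAs detected throughout 1 group. The calls depended on the scaling and on single arrays. A fit without either emodin array leaves 1 emodin array, so its spread comes from the DMSO arrays alone. No miRNA was called in limma with the percentile taken over all probes, with quantile normalization or without scaling (16, 52 and 7 at unadjusted p under 0.05) or with every value raised to its array's lowest detected signal (38), scaling to the labelling spike-in controls gave 0 higher and 44 lower, and 0 were called without emodin replicate 1, where 235 miRNAs passed the filter (4 with the 155 miRNAs and the scaling kept), and 58 without DMSO replicate 2. miR-193b-3p had a log2 fold change of 0.78 without emodin replicate 2, where its adjusted p was 0.346 (over its alternatives 0.00870 to 0.982). Apart from emodin replicate 1, the calls of miR-1273g-3p and miR-6869-5p were lost without emodin replicate 2 (adjusted p = 0.0524 and 0.147), and that of miR-2861 without DMSO replicate 3 or emodin replicate 2 (adjusted p = 0.0846 and 0.0712). Those of miR-4485-5p and miR-6763-5p were lost without DMSO replicate 1 (adjusted p = 0.0619 and 0.0624) or DMSO replicate 3 (adjusted p = 0.106 and 0.111), that of miR-6763-5p also without emodin replicate 2 (adjusted p = 0.137), and that of miR-4306 without DMSO replicate 3 (adjusted p = 0.0862). miR-30c-5p, miR-30b-5p, miR-222-3p, miR-1260a, miR-1260b, miR-4286, miR-7641, miR-6125, miR-197-3p, miR-1234-3p and miR-1973 were the 11 miRNAs called without each of the other 4 arrays. Among them only miR-1260a, miR-1260b, miR-4286 and miR-7641 were detected on all 5 arrays, and all of these are on the list of fragments of other RNAs. The others rest in part on values below detection.

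The miR-29 and miR-30 families, which repress matrix proteins and mediators of epithelial plasticity, lay above the other miRNAs after emodin. Of 9 members tested, 8 had positive values, with a list median of 0.93 against 0.19 for all tested miRNAs, although with spike-in scaling these medians were -1.11 and -1.84. miR-30c-5p and miR-30b-5p rose, and 4 members rose when p was adjusted over the list alone, adding miR-30e-5p and miR-29b-3p. Those had log2 fold changes of 1.84 ± 0.59 and 1.86 ± 0.60 and an adjusted p of 0.0515 each over all miRNAs. The remaining member values ran down to -0.85 for miR-30a-3p, the other arm of the miR-30a-5p precursor, whose 5p arm stood at 0.93. Of the 9 members 5 were detected on 1 of 3 DMSO arrays, among them miR-30b-5p, miR-30c-5p and miR-30e-5p, and with those DMSO values raised to the lowest detected signal the list median was 0.58 and the difference of miR-30e-5p 0.56. The list passed camera with a preset correlation (adjusted p = 0.0440) and not with its estimated correlation of 0.596 (adjusted p = 0.967). Limited to miRNAs detected on all 5 arrays, its camera adjusted p was 0.678. Among other alternatives it did not pass with quantile normalization (0.104), normexp background correction (0.154) or total gene signal (0.192). It passed with scaling over all probes (0.0330) and without scaling (0.0215). It missed the threshold without DMSO replicate 1 (adjusted p = 0.0858), emodin replicate 1 (adjusted p = 0.0759, or 0.0131 with the tested miRNAs and scaling kept) or emodin replicate 2 (adjusted p = 0.129), and with every value raised to its array's lowest detected signal (adjusted p = 0.153), and over the alternatives with a preset correlation its adjusted p ran from 0.00264 to 0.678.

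The let-7 family, whose members share a seed that represses RAS and HMGA2 transcripts, lay below the other miRNAs. All 8 members tested had negative values, from -0.54 for let-7c-5p to -1.57 for let-7e-5p, with a median of -1.01, and let-7e-5p alone fell, as it did when adjusted over the list alone. let-7b-5p had a log2 fold change of -1.12 ± 0.41 (adjusted p = 0.0736), let-7a-5p one of -1.09 ± 0.45 (adjusted p = 0.109) and let-7f-5p one of -1.08 ± 0.48 (adjusted p = 0.120). The list passed camera with the preset correlation of 0.01 (adjusted p = 0.00472). The correlation estimated for its members was 0.821, and with that it did not pass (adjusted p = 0.967). The call of let-7e-5p was lost without DMSO replicate 1 (adjusted p = 0.0573), DMSO replicate 3 (adjusted p = 0.106) or emodin replicate 1 (adjusted p = 0.311), and over its alternatives its adjusted p ran from 0.0134 to 0.979. let-7 members took 10.6%, 23.9% and 10.0% of the total gene signal on the DMSO arrays and 2.42% and 4.72% on the emodin arrays. Such shares also shrink when other signals grow, and miR-7975 and miR-7977 together took a larger share on both emodin arrays than on any DMSO array. The mature let-7 sequences differ by few bases, so their probes can share signal.

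Among miRNAs associated with TGF-beta and epithelial-mesenchymal transition (EMT), 3 of 7 tested members rose, both over all miRNAs and when adjusted over the list alone. They were miR-222-3p, miR-221-3p and miR-181a-5p, of which miR-221-3p and miR-181a-5p had negative values with spike-in scaling, -0.44 and -0.45. The calls of miR-221-3p and miR-181a-5p were also lost without DMSO replicate 1 (adjusted p = 0.0619 and 0.0736), DMSO replicate 3 (adjusted p = 0.180 and 0.106) or emodin replicate 2 (adjusted p = 0.0524 each). Of these, miR-222-3p and miR-221-3p were each detected on 1 of 3 DMSO arrays, and with DMSO values raised to the lowest detected signal their differences were 1.22 and 0.80. miR-196a-5p, detected on 1 of 2 emodin arrays, had a log2 fold change of -0.94 ± 0.41 (adjusted p = 0.120), or -0.47 with emodin values raised, and miR-21-5p, a miRNA raised in many cancers, had 0.38 ± 0.44 (adjusted p = 0.528). The list as a whole did not pass camera (adjusted p = 0.366), and its median of 0.97 became -1.07 with spike-in scaling and, over the same 7 members, 0.49 without emodin replicate 1.

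In the cluster of miR-17 to miR-92a and its paralogous clusters, which include known MYC targets, 1 of 9 members rose, miR-25-3p, also when adjusted over the list alone. miR-92a-3p had a log2 fold change of 1.11 ± 0.43 (adjusted p = 0.0862), while miR-20a-5p and miR-20b-5p had -0.90 ± 0.44 and -0.72 ± 0.45 (adjusted p = 0.154 and 0.255). miR-20b-5p was detected on 1 of 2 emodin arrays and had -0.12 with emodin values raised, and the list did not pass camera (adjusted p = 0.809). Without emodin replicate 2, miR-25-3p had a log2 fold change of 1.85 and an adjusted p of 0.0524 (over its alternatives 0.00243 to 0.979). In hg19 the files map a miR-25-3p probe to chromosome 7, positions 99691239 to 99691255. The probe of its cluster neighbour miR-106b-5p lies at 99691632 to 99691647, and that miRNA had a log2 fold change of -0.17. Of the 11 tested miRNAs reported as higher in cervical cancer miR-25-3p alone rose, also when adjusted over the list alone, and of the 6 reported as lower none was called. For miR-125b-5p of the second list the log2 fold change was 1.28 ± 0.48 (adjusted p = 0.0793), for miR-29a-3p 0.81 ± 0.46 (adjusted p = 0.206) and for miR-23b-3p 0.56 ± 0.42 (adjusted p = 0.336), and the camera adjusted p of these lists was 0.809 and 0.717.

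In 4 other lists no member was called, over all miRNAs or adjusted over the list alone. These were the 5 tested members of the miR-23/27/24 clusters, the 5 of the miR-99/100 and miR-125 families, the 3 of the miR-15/16 family and the 3 p53-responsive miRNAs. Their camera adjusted p values were 0.341, 0.933, 0.809 and 0.809. miR-23a-3p had a log2 fold change of 1.19 ± 0.42 (adjusted p = 0.0677), miR-27a-3p had 1.03 ± 0.50 (adjusted p = 0.146) and miR-27b-3p 0.69 ± 0.48 (adjusted p = 0.299). miR-34a-5p, a direct p53 target, had 0.67 ± 0.50 (adjusted p = 0.335) and miR-107 -0.10 ± 0.42 (adjusted p = 0.843). miR-192-5p, detected on 2 of 3 DMSO arrays, had 0.51 ± 0.51 (adjusted p = 0.468), which turned to -0.62 with DMSO values raised. The largest values of the miR-99/100 and miR-125 families were those of miR-125b-5p and miR-100-5p, at 1.28 and -0.29 ± 0.43 (adjusted p = 0.654 for the latter), with miR-99b-5p at 0.15 and miR-125a-5p at -0.12. In the miR-15/16 family miR-16-5p had -0.54 ± 0.43 (adjusted p = 0.355), with miR-15a-5p at 0.19 and miR-15b-5p at 0.11. The miR-15/16 family had a mean of -0.08 and a median of 0.11, so its direction differed between them, and camera's direction was down. Lists with under 3 tested members had no list test. Of these, miR-193b-3p rose in the hypoxia and redox list, also when adjusted over the list alone, while miR-210-3p, the main hypoxia-induced miRNA, had -0.48 ± 0.42 (adjusted p = 0.405). The inflammation list had 2 tested members, miR-125b-5p and miR-21-5p, of which miR-125b-5p passed when adjusted over the list alone (adjusted p = 0.0410), though without emodin replicate 2 its log2 fold change went from 1.28 to 0.60. The stromal list had 1, miR-10b-5p at -0.45 ± 0.42 (adjusted p = 0.438). The 14q32 cluster had 1, miR-494-3p at 1.48 ± 0.62 (adjusted p = 0.109), so that its p adjusted over the list alone, 0.0337 in limma, is the unadjusted one. Its groups overlapped, and without emodin replicate 2 its value was 0.35. No member of the epithelial miR-200 family list, of the C19MC cluster or of the markers of other cell types passed the detection filter.

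Entries that overlap fragments of tRNA, rRNA and other abundant RNAs went both ways. Of 10 tested, 4 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone. Those that rose were miR-1260a (2.47 ± 0.59, adjusted p = 0.0234), miR-4286 (2.16 ± 0.53, adjusted p = 0.0234), miR-1260b (1.86 ± 0.52, adjusted p = 0.0346) and miR-7641 (1.79 ± 0.46, adjusted p = 0.0234), and the one that fell was miR-1973, which resembles mitochondrial sequence. With spike-in scaling miR-1260b and miR-7641 had -0.17 and -0.25. Without emodin replicate 1 the values of miR-1260a, miR-4286 and miR-1260b were 1.52, 1.40 and 1.09 (adjusted p = 0.230, 0.232 and 0.305), and the list's median over its 10 members was 0.92. The list alone added miR-7977 and miR-3656, of which miR-3656 was not detected on any DMSO array and its bound did not exceed no change. The list's median was 1.42, or 1.18 with the member not detected in DMSO set at no change, and -0.62 with spike-in scaling, and it did not pass camera (adjusted p = 0.0763). Without DMSO replicate 1, DMSO replicate 3 or emodin replicate 2 it passed (adjusted p = 0.0403, 0.0298 and 0.0461), and over the alternatives with a preset correlation its adjusted p ran from 0.00225 to 0.417. With an estimated correlation its adjusted p was 0.967. miR-7975 and miR-7977, named for their signal in DMSO, had log2 fold changes of 1.14 ± 0.51 (adjusted p = 0.120) and 1.22 ± 0.50 (adjusted p = 0.109). Together they took 63.9%, 39.8% and 65.6% of the total gene signal in DMSO replicates 1, 2 and 3, and 75.7% and 70.1% in emodin replicates 1 and 2. Of other entries named for their signal, miR-5100 had 1.22 ± 0.49 (adjusted p = 0.0949), miR-6826-5p -0.52 ± 0.47 (adjusted p = 0.415) and miR-5739 -0.27 ± 0.51 (adjusted p = 0.712).

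GC-rich array miRNAs, whose signal is known to vary with RNA quality and input, had 3 calls among 30 tested members, miR-6125, miR-2861 and miR-6869-5p, and none when adjusted over the list alone. miR-7704, detected on 1 of 3 DMSO arrays, had a log2 fold change of 1.54 ± 0.49 (adjusted p = 0.0511), or 1.49 with DMSO values raised, and the list did not pass camera (adjusted p = 0.794). Within the vehicle group this list stood apart on 1 array, with a median log2 difference of -1.25 in DMSO replicate 2 from the mean of DMSO replicates 1 and 3. The same difference was 0.72 for the let-7 family, 0.92 for the miR-29 and miR-30 families and -0.93 for the fragment list. Emodin replicate 2 minus emodin replicate 1 gave medians of the same sign for these, 0.34, 0.30 and -0.73. For the GC-rich list it gave the opposite sign, 0.15, and for all tested miRNAs 0.22.

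**Figure D2:**
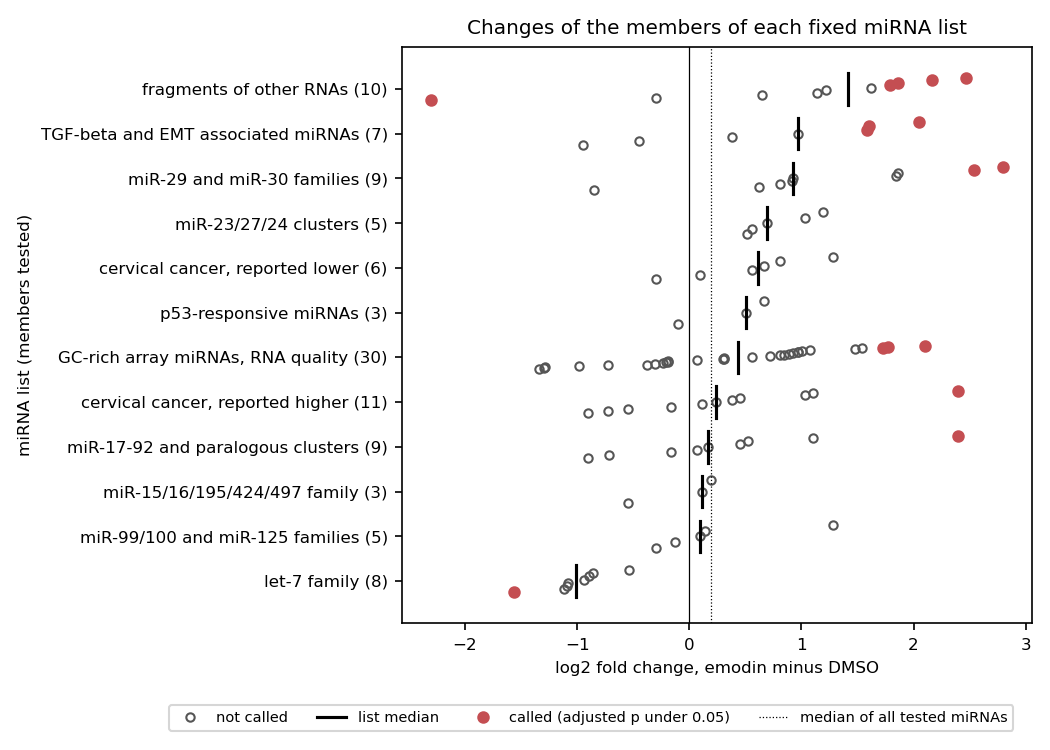
Log2 fold change, emodin minus DMSO (horizontal axis), of each tested member of the 12 lists tested (vertical axis, members in brackets), where filled points are called miRNAs, open points are not called, thick bars are list medians and the dotted line is the median of all tested miRNAs, 0.19. The let-7 median lies at -1.01. With spike-in scaling all 12 medians lie below 0, as does the median of all tested miRNAs (-1.84).

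**Figure D3:**
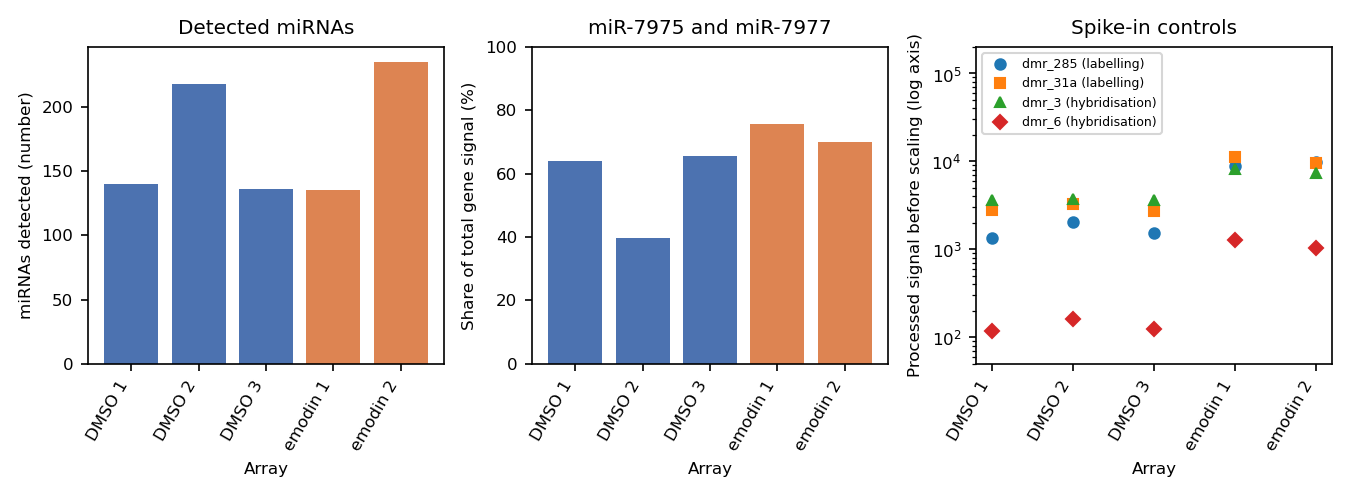
Detected miRNAs per array (left), percent of the total gene signal taken by miR-7975 and miR-7977 (middle) and processed signal of 4 spike-in controls before scaling on a log axis (right), with DMSO arrays blue and emodin arrays orange in the bar plots. DMSO replicate 2 and emodin replicate 2 have 218 and 235 detected miRNAs, against 135 to 140 on the other arrays.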

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

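The tests of the vehicle arrays' composition and of the spike-in controls were chosen only after the result was seen. The 4 spike-in controls, which stand outside the miRNA measurements, were brighter on both emodin arrays than on every DMSO array before scaling. The log2 difference, emodin minus DMSO, was 2.54 for dmr_285 and 1.83 for dmr_31a, which are added before labelling. It was 1.09 for dmr_3 and 3.13 for dmr_6, which are added before hybridisation. An exact two-sided permutation test gave p = 0.1 for each, the smallest value that 3 against 2 arrays allow.

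A single brightness factor, equal for all controls on the emodin slide, is argued against, since the 4 differences spanned 2.04 on the log2 scale. The dimmer a control was in DMSO, the larger its difference. The DMSO means were 7.05 for dmr_6, 10.65 for dmr_285, 11.51 for dmr_31a and 11.83 for dmr_3. A slide-wide difference whose size depends on brightness was not tested and stays open. The median difference before scaling of the 108 miRNAs detected on all arrays was 0.24. Less small RNA per total RNA after emodin, a candidate biological explanation, is argued against for the hybridisation controls, whose smaller difference was 1.09, and each of these differences was at least 13.1 times that control's SD over the DMSO arrays. For the labelling controls it cannot be told apart from a handling difference between slides, because their mean difference exceeded that of the hybridisation controls by 0.0769, well within the range over the 4.

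The second pattern is a lower let-7 family and higher miR-29 and miR-30 families after emodin, though with spike-in scaling the latter had a median of -1.11, and 5 of their 9 members were detected on 1 of 3 DMSO arrays. DMSO replicate 2 differed in composition from DMSO replicates 1 and 3, but both families lay on one side of that difference (medians 0.72 and 0.92) while their emodin changes had opposite signs, and in contrasts that share no array the emodin change correlated with it across the 155 tested miRNAs at 0.249 and 0.204 (95% intervals 0.0952 to 0.391 and 0.0475 to 0.350; miRNAs are not independent replicates), chosen after a first correlation between contrasts that share the DMSO arrays had given -0.0124. DMSO replicates 1 and 3 resembled each other, so what they share enters both contrasts and can itself give a positive correlation. The opposite signs and the low correlations argue against that difference as the whole cause but not against a part in the changes. A trend on probe GC content as the whole cause is argued against by the distance between the families' median changes, which went from 1.94 to 1.73 when the trend was removed. The number of slides holding both groups is 0, so a difference between slides cannot be told apart from a response to emodin, which stays open as untested. Of the 10 splits of the 5 arrays into 3 and 2, 1 gave as many calls as the real 24, namely the real one, and the highest of the others was 0, and 10 splits are too few for a share under 0.05.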

How the results depend on the processing

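The alternatives of spike-in scaling, scaling without the GC-rich and fragment lists, GC trend removal, averaging of DMSO replicates 1 and 3, keeping outlier spots, centring the value table, raising every value to its array's lowest detected signal and leaving out emodin replicate 1 with the tested miRNAs and scaling kept were chosen after seeing the data. Against 24 changed miRNAs (19 higher, 5 lower), limma called 0 (0 higher, 0 lower) with scaling over all probes, quantile normalization, no scaling, normexp background correction, the value table as deposited, values raised to the lowest detected signal, and no filter on dim miRNAs. At unadjusted p under 0.05 these gave 16, 52, 7, 12, 14, 38 and, of 2549 tested, 330 miRNAs, against 59 in the main setting. The brightest probe gave 8 (6 higher, 2 lower), total gene signal 2 (2 higher, 0 lower), the value table after centring 2 (2 higher, 0 lower) and scaling without the GC-rich and fragment lists 8 (7 higher, 1 lower). GC trend removal gave 54 (34 higher, 20 lower), of which 23 were among the main 24. Detection on all 5 arrays gave 9 lower of 22, a floor of 5 gave 13 lower of 36, and averaging DMSO replicates 1 and 3 gave 2 lower of 19. An intensity trend with a robust prior gave 25 (18 higher, 7 lower), with 20 of the main 24 among them and the calls of miR-197-3p, miR-1973, miR-2861 and miR-1234-3p lost. The cause was not tested for these, except that the filters change how many miRNAs are adjusted for. All 24 main calls kept their sign in every alternative that tested them except spike-in scaling, where 13 did, and raised values, where 23 did and miR-1234-3p (-0.07) did not. Detection on all arrays tested 14 of them.

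Scaling to the labelling spike-ins, which moved the median of all tested miRNAs from 0.19 to -1.84, gave 44 changed (0 higher, 44 lower). It reversed miR-193b-3p (-0.0314), miR-1260b (-0.17), miR-7641 (-0.25), miR-6869-5p (-0.27), miR-1273g-3p (-0.28), miR-221-3p (-0.44), miR-2861 (-0.31), miR-197-3p (-0.23) and miR-181a-5p (-0.45), and of the called miRNAs outside the naming rule miR-425-5p (-0.54) and miR-22-3p (-0.65). By construction it lowers miRNAs well above the floor by about the same amount, and some dim ones by less. miR-1273g-3p went from 1.76 to -0.28, but miR-30c-5p from 2.80 to 1.18 and miR-1973 from -2.30 to -3.74. The medians of all tested miRNAs were 0.49 with scaling over all probes, 0.28 without scaling, 0.05 with quantile normalization, 0.00129 with normexp, -0.02 with the brightest probe and -0.62 with the value table as deposited. With those deposited values 9 of 12 list medians lay below 0, and let-7 lay below and the miR-29/30, fragment and TGF-beta lists above 0 as in the main setting.

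Leaving out 1 array at a time gave 0 to 58 changed miRNAs, 0 to 35 higher, 0 to 23 lower and 1 to 3 lists. Without emodin replicate 1 there were 0 (44 at unadjusted p under 0.05) and 1 list, but 235 miRNAs passed the filter and the scaling changed too. With the 155 miRNAs and the scaling kept there were 4 (4 higher, 0 lower; 34 at unadjusted p under 0.05), with 3 of the main 24 among them, and 2 lists. In both, and in the fit without emodin replicate 2, the lone emodin array was assumed to vary like the DMSO arrays. Without DMSO replicate 2 there were 58 (35 higher, 23 lower), without DMSO replicate 1 there were 2 lower, without DMSO replicate 3 also 2 lower, and without emodin replicate 2 there were 12 higher. Of the 24 calls, 11 were kept without each of the 4 arrays other than emodin replicate 1. The calls lost had adjusted p from 0.0573 to 0.106 without DMSO replicate 1 (7 lost), 0.0846 to 0.245 without DMSO replicate 3 (9 lost), 0.0524 to 0.346 without emodin replicate 2 (10 lost) and 0.0609 to 0.458 without emodin replicate 1 (24 lost).

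Against 2 called lists, 1 was called with quantile normalization, the brightest probe, total gene signal, a floor of 5, outlier spots kept, raised values and the centred value table. Scaling over all probes, normexp background correction and spike-in scaling each called 3. The value table as deposited, camera with an estimated correlation and fry each called 0. let-7 passed camera in every alternative with a preset correlation (adjusted p from 1.34e-06 to 0.0298) except the value table as deposited (adjusted p = 0.0710). The adjusted p of the miR-29 and miR-30 list ran from 0.00264 to 0.678 with a preset correlation and was 0.967 with an estimated one. With the replicate number as a block, 19 miRNAs changed (17 higher, 2 lower) with 3 lists, and 16 of the 19 were among the main 24. Same-numbered arrays correlated at 0.108 and 0.199 in their deviations from the group means. The highest value, 0.281, was between arrays of unlike number, DMSO replicate 3 and emodin replicate 1. With 2 emodin arrays, the values of each DMSO array with them are equal in size and opposite in sign. These correlations therefore do not show whether the numbers pair the samples. A slide block was not run, because each slide holds 1 group. Signal over background limits the dim miRNAs, since 108 of the 155 tested were detected on all 5 arrays. Of the 24 calls, 14 were of miRNAs detected on all 5, 6 of miRNAs detected on some arrays of 1 group and 4 of miRNAs not detected in DMSO.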

Other observations

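The test that split neighbouring miRNAs by likeness of sequence was chosen only after the result was seen. Of the 24 called miRNAs, 3 fall outside the naming rule and were chosen after their values were seen. miR-425-5p had a log2 fold change of 1.49 ± 0.45 (adjusted p = 0.0426) and miR-22-3p, a miRNA reported to restrain growth in several cancers, 1.39 ± 0.43 (adjusted p = 0.0473). With spike-in scaling miR-425-5p and miR-22-3p had values of -0.54 and -0.65. Both calls were lost without DMSO replicate 1 (adjusted p = 0.106 each), DMSO replicate 3 (adjusted p = 0.180 and 0.245), emodin replicate 1 (adjusted p = 0.146 and 0.229) or emodin replicate 2 (adjusted p = 0.204 and 0.119). miR-1234-3p was higher (adjusted p = 0.0234) but not above background on any DMSO array, and its bound did not exceed no change. With all arms and neighbours on the same scaling, several precursors and clusters gave unequal values. In the cluster of miR-17 to miR-92a on chromosome 13, miR-92a-3p stood at 1.11 and miR-20a-5p at -0.90, 290 bases apart, with miR-17-5p at 0.07 and miR-19b-3p at 0.17. On chromosome 16 miR-193b-3p stood at 1.95 and its neighbour miR-365a-3p at -0.21. On chromosome 19 let-7e-5p stood at -1.57, and miR-99b-5p, 172 bases away, at 0.15. The differences between members of these pairs were not tested.

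One hypothesis was that miRNAs from one stretch of the genome change together after emodin. Among 78 placed miRNAs, 33 pairs within 10 kb on 1 strand had a mean absolute difference in log2 fold change of 0.904, against a median of 1.22 when values were permuted (100000 one-sided permutations, p = 0.0248). Pairs follow the files' unchecked positions, by which miR-93-5p is not a neighbour of miR-25-3p or miR-106b-5p. The 11 pairs of 1 family and arm, such as miR-221-3p with miR-222-3p and let-7a-5p with let-7f-5p, had a mean of 0.660 (permutation p = 0.0126). The other 22 pairs, of different families or, in 4 cases, opposite arms of 1 precursor, had 1.03 (permutation p = 0.172). Of these, miR-939-5p with miR-1234-3p differed most, by 3.08, and miR-1234-3p was not detected in DMSO. The 22 pairs were not tested without it. The 32 pairs of any kind with both members detected in both groups had a mean of 0.835 (permutation p = 0.0140). Near-identical sequence within families may account for the likeness, while joint transcription stays open, since pairs of 1 family are also transcribed together and the difference between the kinds of pair was not tested.

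Probe GC content ran with the difference between DMSO replicate 2 and DMSO replicates 1 and 3 across the 155 tested miRNAs (Spearman -0.836) and less with the emodin change (0.167). Across miRNAs, which are not independent replicates, these are descriptions of the arrays and no explanation was tested.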
